A study of Mus musculus with 12 samples.

How the data were processed

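RNA sequencing libraries of granule cell progenitors from control and Znhit3 cKO mice were compared at P3, with 3 libraries per group. Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented and made into dUTP-marked libraries for paired-end sequencing. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6 with the genome build mm10, and also DESeq2 and edgeR without versions, with no role or order given for any of them. The annotation, the filters and the use of strand in counting are not given in the sources used here. Without a stated use of strand, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes or the haemoglobin genes, carry the same doubt.

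The authors deposited 1 table for P3 with 31091 genes. Its sample columns hold FPKM values made by the authors, 3 for control and 3 for cKO. The cKO columns carry a 2-letter prefix that was taken as cKO because the remaining columns of the table are named WT and the labels list no other P3 samples. Multiplied by the deposited gene length (Length_CDS, per the file header), all FPKM values were whole multiples of 1 read within 0.02 reads. This gave the library depths in the report. Gene length below means this value and not the span on the chromosome. At these depths a count of 3 reads in a gene of 1 kb corresponds to between 0.057 and 0.10 FPKM, a floor that covers counting error only. The table also holds a comparison by the authors, with a mean signal per gene over all libraries, a log2 fold change with its standard error, a test score and a p-value with its adjusted value, per the file headers. The column names are those that DESeq2 writes, per the file headers, and the authors' adjusted p-values matched a Benjamini-Hochberg adjustment over 16021 genes. The adjusted value was exactly 1 for the other 15070 genes, which had the lowest mean signal and were read as not tested by the authors. The authors' table called 3695 genes at an adjusted p under 0.05, 1834 higher and 1861 lower.

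Positions are printed as the deposited table gives them. Of 29560 genes shared with the GRCm38 annotation by identifier, 614 had the same start and end, so the build of these positions is not stated here although the processing notes name mm10. No position from another annotation was printed.

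The unit is FPKM and not counts, so tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and no covariates. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 13538. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a size filter of 2-fold was applied to the same fit. Znhit3 was also tested with an exact permutation test. The libraries of a group differed beyond counting noise in every pair, with a chi-square per degree of freedom between 4.38 and 9.71, so no library was counted as a duplicate. The 10 most abundant genes took between 3.94% and 4.33% of the reads of a library.

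The groups, the tests, the main alternatives, 35 gene lists and the rule for named genes were fixed before the data were examined. Of 981 list entries 946 matched a symbol in the table, 29 a GENCODE symbol and 2 a RefSeq synonym, and 4 were not matched. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists. The rule named Znhit3 and, among called genes with a mean of at least 5 FPKM in the higher group, no overlap between groups and a symbol that is not a Gm number, a Rik clone, a Rpl or Rps pseudogene or missing, the 10 with the largest rise and the 10 with the largest fall. It also named up to 3 called members with the smallest p from each list, or the most abundant member where none was called, and up to 5 called genes within 2 Mb of Znhit3 by smallest p. Other genes in the text were chosen after their values were seen, namely Trp53, Atoh1, Gli1, Mycn, Rgcc, Nfix, Hmgb1, Rps18-ps5, Eif2s3y, Kdm5d, Uty and those of the closing section. Some genes that the rule names are not reported here.

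Alternatives fixed in advance were another pseudocount, other filters, upper quartile, quantile and TPM scaling, limma without the trend, array weights, a replicate block, leaving out each library, a 1.5-fold filter, camera with an estimated correlation and fry. Camera with an estimated correlation takes its degrees of freedom from the few libraries rather than from the genes, so it has less power here. Removal of length and GC trends, voom on the recovered reads, protein-coding genes only and omission of X and Y were added after seeing the data. The fit was tested on simulated data with reads for the real genes and 200 genes changed by known folds. Of 50 tested genes per fold size it recovered 60.0% at 1.25-fold, 96.0% at 1.5-fold and 100.0% at 2-fold and at 3-fold for cKO against control at P3. There were 6.81% false calls among 191 calls over 13561 genes. Reads were drawn independently for each gene, with 1 dispersion (0.00299) and no trend with gene length. These rates thus may not hold for the real libraries.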

Results

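RNA was sequenced from granule cell progenitors, the dividing precursors of cerebellar granule neurons, of control mice and of mice with a conditional knockout (cKO) of Znhit3. The series holds 12 samples, with 3 control and 3 cKO samples at postnatal day 3 (P3) and as many at postnatal day 6 (P6). The P6 libraries were not analysed here, so every value below is from the 6 P3 libraries. The deposited FPKM values corresponded to 40714149, 32278245 and 52961445 counted reads in control replicates 1 to 3 and to 37514556, 40281292 and 29119803 in cKO replicates 1 to 3. The labels do not say whether replicates came from separate animals. The p-values therefore measure the spread between these samples, which may be partly or wholly technical. Differences are cKO minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values are from limma unless stated otherwise.

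The comparison at P3 asked how loss of Znhit3, which encodes a zinc-finger protein known as an assembly factor of box C/D small nucleolar ribonucleoproteins (snoRNPs), altered transcription in these progenitors. Znhit3 itself (ENSMUSG00000020526, chromosome 11, 84801776 to 84807192, minus strand, as the deposited table gives the position) measured 9.15, 8.62 and 8.58 FPKM in the control libraries and 4.03, 4.01 and 4.57 FPKM in the cKO libraries. The mean fell from 8.78 ± 0.32 (SD, n = 3) to 4.20 ± 0.32 FPKM (SD, n = 3), which left 47.8% of the control level. All 3 cKO values lay below all 3 control values. The exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 samples allow, and the fit across all genes gave a log2 difference of -0.91 ± 0.06 (SE) with an adjusted p of 0.00024. In the authors' deposited table the log2 fold change of Znhit3 was -1.12. The value counts reads over the whole gene, so exons outside any deleted part contribute to it.

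Cdkn1a, which encodes the cell cycle inhibitor p21, showed the largest rise among the genes named by the rule fixed in advance, from 6.58 ± 0.19 to 21.8 ± 0.57 FPKM (SD, n = 3), a log2 difference of 1.59 ± 0.04 (SE) with an adjusted p of 2.4e-06. Phlda3, a p53-induced repressor of Akt signalling, rose from 3.00 to 7.35 FPKM, and Eda2r, a p53-induced receptor of the tumour necrosis factor receptor family, rose from 3.43 to 7.48 FPKM. The proneural transcription factor gene Neurog2 rose from 5.92 to 12.2 FPKM, the myogenic transcription factor gene Myod1 from 2.75 to 7.17 FPKM and Aplnr, the apelin receptor gene, from 13.7 to 27.1 FPKM. Among the falls, Ttr, the transthyretin gene expressed strongly in choroid plexus, went from 1370 ± 48 to 665 ± 44 FPKM (SD, n = 3), and the water channel gene Aqp1 from 7.37 to 3.26 FPKM. Scg2, which encodes a secretory granule protein, fell from 16.1 to 8.53 FPKM, and the somatostatin receptor gene Sstr2 fell from 61.9 to 35.4 FPKM.

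The other named falls were Sostdc1, an inhibitor of BMP signalling (6.13 to 3.04 FPKM), the chloride channel gene Clic6 (5.81 to 2.89 FPKM), the pseudogene Hmgb1-ps7 (42.6 to 11.7 FPKM), Mir99a (6.67 to 1.63 FPKM) and Xist, the RNA that silences an X chromosome in female cells (53.7 to 24.0 FPKM). The other named rises were the Y-linked helicase gene Ddx3y (5.28 to 12.4 FPKM), Rn7sk (4.04 to 9.14 FPKM), Mir7664 (1.68 to 5.13 FPKM) and Snord88c (3.61 to 7.28 FPKM). The last 2 and Mir99a rested on few reads: between 2 and 16 per library for Mir7664, 6 and 26 for Snord88c, and 0 and 30 for Mir99a. Rn7sk had between 27 and 119 reads per library. Mir7664, Mir99a, Snord88c and Rn7sk span 63, 65, 90 and 331 bases, and the libraries were made from poly(A)-selected RNA. Whether their reads came from the small RNAs themselves or from overlapping transcripts was not tested. Reads of Hmgb1-ps7 can be shared with its parent gene Hmgb1, which measured 261 and 242 FPKM with an adjusted p of 0.16.

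**Figure D1:**
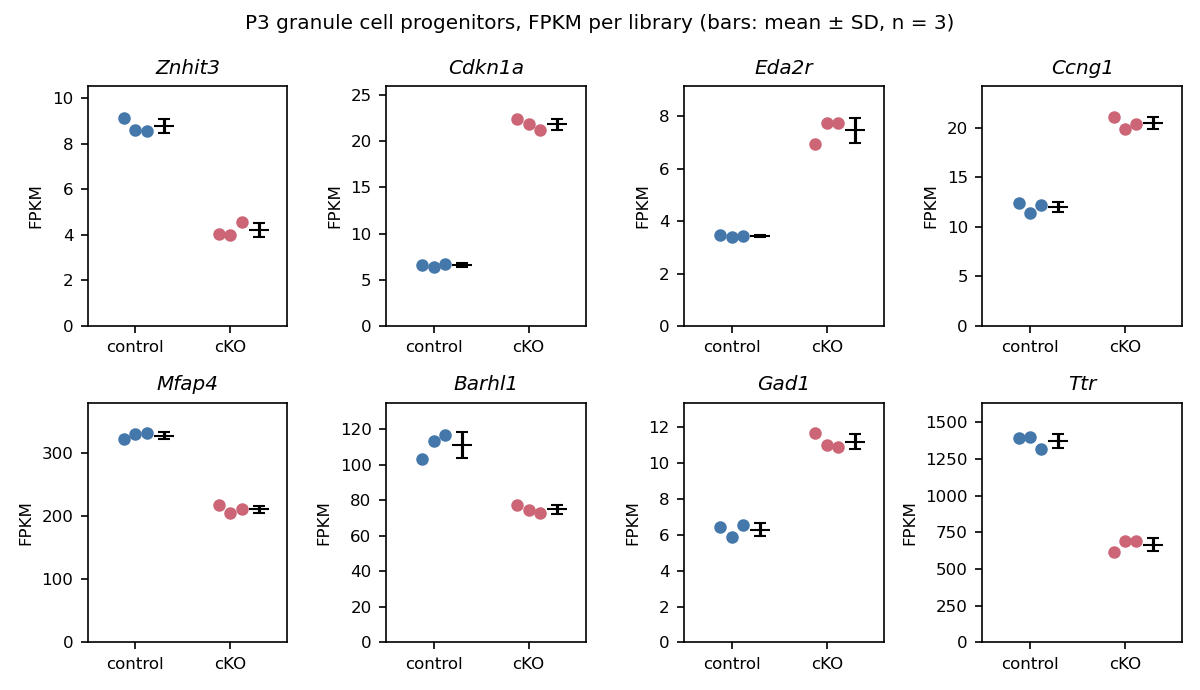
FPKM (vertical axis, from 0) of 8 genes in each of the 3 control and 3 cKO libraries at P3, with bars for the mean ± SD beside the points. Znhit3 fell from 8.78 to 4.20 FPKM and Cdkn1a rose from 6.58 to 21.8 FPKM, and in each of the 8 panels the points of the 2 groups did not overlap.

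Of 13538 genes tested, 2590 changed at P3, with 1813 higher and 777 lower in cKO, so 70.0% of the changed genes were higher. Most changes were small: 196 of them reached 1.5-fold and 23 reached 2-fold, 10 higher and 13 lower. These counts were 431 and 61 (35 higher and 26 lower at 2-fold) with a pseudocount of 0.1, 482 and 75 (41 and 34) with voom and 415 and 48 (31 and 17) with TPM scaling. They were 98 and 13 at a mean of at least 5 FPKM, and 139 and 8 among protein-coding genes. Of the 23, 8 were protein-coding genes, among them Cdkn1a, Phlda3, Myod1, Ddx3y and Ttr, and 9 were pseudogenes. The 3 cKO values lay all above or all below the 3 control values in 40.5% of tested genes, where chance gives 10%. The count of changed genes fell to 1331 without control replicate 2, 1490 without control replicate 3, 1207 without cKO replicate 2, 1553 without cKO replicate 3 and 1271 with no filter on low values. It rose to 3721 with array weights, 3718 with voom, 3171 among protein-coding genes and 2997 with TPM scaling. The share that was higher was 56.8% after quantile normalization, 81.7% after TPM scaling and 52.6% after removal of a gene length trend. The median difference over all tested genes was 0.03, and the authors' calls among these genes were 1637 higher and 1814 lower. The balance of rises and falls thus depended on the scaling and the method.

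**Figure D2:**
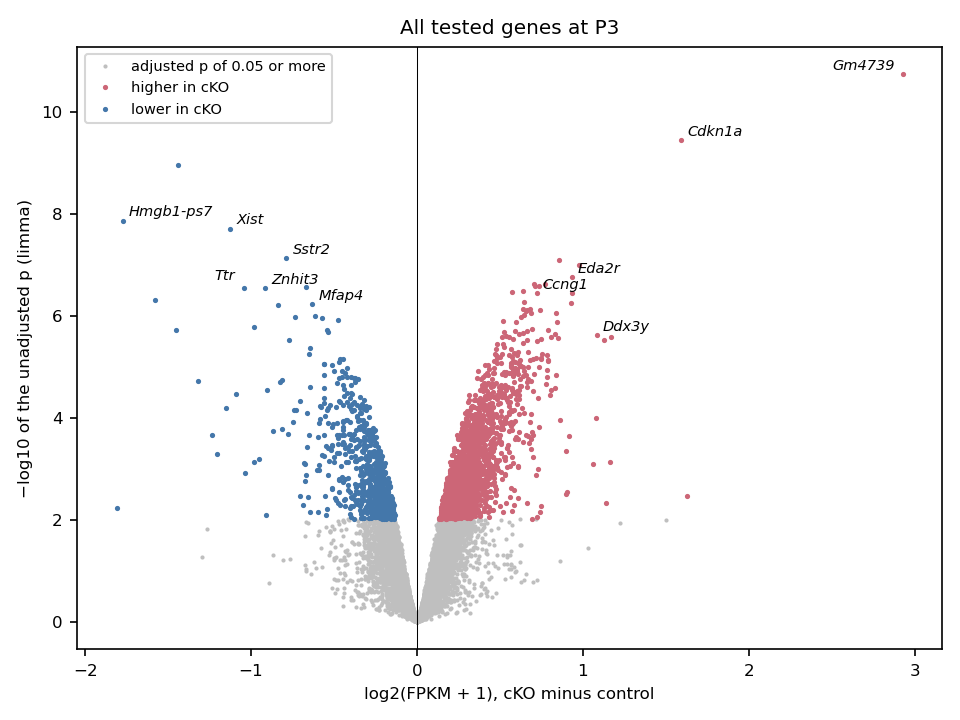
Each point is a tested gene at P3, with the cKO minus control difference in log2(FPKM + 1) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis. Red points are the 1813 genes higher and blue points the 777 genes lower in cKO at an adjusted p under 0.05, and Cdkn1a stands far to the right at 1.59.

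Of 46 measured targets of the transcription factor p53, 26 rose, 1 fell and 19 did not pass the test, and adjusted over the list alone 32 rose and 1 fell. After Cdkn1a and Eda2r, the strongest evidence was for Ccng1, which encodes cyclin G1 and rose from 12.0 ± 0.52 to 20.5 ± 0.63 FPKM (SD, n = 3). The list median was 0.28, with an adjusted camera p of 2.0e-10 at the preset correlation and an adjusted p = 0.071 with an estimated correlation. In the same libraries the marker lists of 8 other cell types had medians between 0.25 and 0.63. Trp53 itself measured 38.4 and 41.5 FPKM with an adjusted p of 0.21. Among 27 apoptosis regulators, 6 rose and 1 fell (8 and 2 adjusted over the list alone), and camera gave an adjusted p of 0.50 (adjusted p = 0.66 with an estimated correlation). Hrk, a pro-apoptotic BH3-only gene, rose from 1.61 to 2.44 FPKM, Casp8 rose from 4.78 to 6.32 FPKM, and Bcl2l1, which encodes the survival protein Bcl-xL, fell from 29.0 to 24.2 FPKM.

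None of the 8 box C/D assembly factors passed limma's threshold over all genes or adjusted over the list alone, and the most abundant, Hsp90ab1, measured 1007 and 913 FPKM with an adjusted p of 0.12 (camera adjusted p of 0.093, and adjusted p = 0.25 with an estimated correlation). The list named snoRNP core proteins, with 12 members, also holds the assembly factors Naf1 and Shq1 and the nucleolar proteins Nolc1 and Tcof1. Of its members only Snu13, which binds the box C/D motif, fell, from 53.5 to 47.8 FPKM with an adjusted p of 0.049. None passed adjusted over the list alone. The box C/D core genes Fbl, Nop56 and Nop58 had differences of -0.11, -0.13 and -0.03 and were not called. The 3 positive differences were those of Naf1, Tcof1 and Nolc1. That list fell relative to other genes with an adjusted camera p of 0.037, and with an adjusted p = 0.25 with an estimated correlation. After length and GC correction its adjusted camera p was 0.055. Among 18 non-coding host genes of snoRNAs, Snhg5 fell from 18.6 to 14.0 FPKM, Snhg20 fell from 6.71 to 5.10 FPKM and Snhg15 rose from 2.80 to 3.60 FPKM, and the counts were the same adjusted over the list alone. The host gene list had an adjusted camera p of 0.010 and an adjusted p = 0.12 with an estimated correlation. In the same libraries 8 marker lists of other cell types had medians between 0.25 and 0.63.

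Some transcripts of cytosolic ribosomal proteins and of the nuclear-encoded respiratory chain were lower. Of 80 ribosomal protein genes 18 fell and none rose, and adjusted over the list alone 26 fell. Rps18 fell from 151 ± 12 to 107 ± 4.2 FPKM (SD, n = 3), Rpl14 from 301 to 243 FPKM and Rpl35a from 56.8 to 41.5 FPKM. The list median was -0.18, with an adjusted camera p of 6.2e-14 and an adjusted p = 0.12 with an estimated correlation. With quantile normalization that median was -0.060 and the adjusted camera p was 0.012. Reads of these genes can be shared with their many processed pseudogenes: Rps18-ps5 rose from 18.7 to 37.7 FPKM while Rps18 fell. Of 51 respiratory chain genes 9 fell and none rose, with the same 9 lower in number adjusted over the list alone, a median of -0.16, an adjusted camera p of 8.7e-11 and an adjusted p = 0.12 with an estimated correlation. Atp5c1, a subunit of ATP synthase, fell from 151 to 129 FPKM, Ndufb9 of complex I from 22.1 to 17.6 FPKM and Cox6c of complex IV from 37.6 to 31.1 FPKM.

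None of the 13 mitochondrially encoded genes passed limma's threshold over all genes or adjusted over the list alone, and mt-Co1 measured 6655 and 6896 FPKM with an adjusted p of 0.74. Their camera p was 0.95 after adjustment, with an adjusted p = 0.98 with an estimated correlation. Factors of ribosome biogenesis gave 6 rises and 1 fall among 87 members and none adjusted over the list alone, with an adjusted camera p of 0.83 and an adjusted p = 0.93 with an estimated correlation. Among them Ddx21, a nucleolar helicase gene, rose from 26.5 to 30.5 FPKM and Utp20 from 3.92 to 4.81 FPKM, while Emg1, which encodes a methyltransferase of 18S ribosomal RNA, fell from 26.2 to 22.4 FPKM.

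Cholesterol synthesis genes were lower in part. Of 20 members 9 fell and none rose, and adjusted over the list alone 10 fell. Fdft1, which encodes squalene synthase, fell from 35.6 ± 2.1 to 24.9 ± 0.69 FPKM (SD, n = 3), Fdps from 23.3 to 17.7 FPKM and Nsdhl from 20.2 to 16.5 FPKM. The median was -0.19, the adjusted camera p was 1.1e-06, and the list had an adjusted p = 0.071 with an estimated correlation. Beside this, marker lists of 8 other cell types had medians of 0.25 to 0.63 and that of choroid plexus and ependyma -0.74. The same holds for the ribosomal protein and respiratory chain genes.

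Of 55 mitosis and G2/M genes 7 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.08, an adjusted camera p of 1.4e-05 and an adjusted p = 0.16 with an estimated correlation. That median was -0.05 with TPM scaling and -0.13 after removal of a gene length trend. These shifts and those of S phase genes came from libraries in which the medians of 8 marker lists of other cell types were 0.25 to 0.63. Birc5, which encodes survivin, fell from 32.5 to 26.8 FPKM and Cdc20, an activator of the anaphase-promoting complex, from 101 to 84.6 FPKM, whereas Ckap2 rose from 29.4 to 35.7 FPKM. Of 48 replication and S phase genes 3 rose and 3 fell (3 and 2 adjusted over the list alone), including falls of E2f1 (53.7 to 41.6 FPKM) and rises of E2f8 (6.41 to 8.02 FPKM) and Ccne2 (9.07 to 12.2 FPKM). That list's median was -0.03, its adjusted camera p was 0.045, and it had an adjusted p = 0.47 with an estimated correlation. With TPM scaling its median was 0.01 and its camera p was 0.13 after adjustment. After removal of a gene length trend its median was -0.07 and its adjusted camera p was 0.0098. Of 9 histone genes H2bc11 fell from 4.88 to 3.12 FPKM, 1 gene over all genes and 1 adjusted over the list alone, with an adjusted camera p of 0.034 and an adjusted p = 0.17 with an estimated correlation. The histone median was -0.13, and after removal of a gene length trend it was -0.06 with an adjusted camera p of 0.39.

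Progenitor and differentiation markers of the granule lineage changed in part, in libraries where marker lists of 8 other cell types had higher medians, up to 0.61 for GABAergic interneurons and 0.63 for endothelium. Mfap4 fell from 327 ± 5.3 to 211 ± 5.9 FPKM (SD, n = 3), and the granule lineage transcription factor genes Barhl1 (111 to 74.8 FPKM) and Pax6 (44.6 to 36.4 FPKM) fell. Rgcc and Nfix were among the rises, and Atoh1, the gene of the transcription factor that specifies these progenitors, measured 37.5 and 35.0 FPKM with an adjusted p of 0.36. Of 17 progenitor markers 3 rose and 3 fell, and adjusted over the list alone 3 rose and 7 fell, with a median of -0.11, an adjusted camera p of 0.0018 and an adjusted p = 0.34 with an estimated correlation. Of 32 markers of differentiating granule neurons 10 fell and 2 rose (12 and 7 adjusted over the list alone), with Cbln1, a synaptic organiser gene, at 87.7 and 63.3 FPKM, the neurofilament gene Nefm at 11.8 and 8.55 FPKM, and the kainate receptor gene Grik2 at 7.48 and 5.29 FPKM. Their median was -0.03, the adjusted camera p was 0.0074, and the list had an adjusted p = 0.33 with an estimated correlation. Of 42 synapse genes 12 fell and 4 rose (12 and 5 adjusted over the list alone), with falls of Stmn2 (83.8 to 57.6 FPKM), Snap25 (9.92 to 7.77 FPKM) and the AMPA receptor gene Gria2 (log2 difference -0.41). The synapse median was -0.03, with an adjusted camera p of 0.0048 and an adjusted p = 0.095 with an estimated correlation. With TPM scaling the medians of the differentiation and synapse lists were 0.01 each, while both lists stayed below the other genes in camera. With quantile normalization the synapse median was -0.08, and the progenitor and differentiation lists had adjusted camera p-values of 0.10 and 0.11.

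Readouts of Sonic hedgehog signalling, the main mitogen of these progenitors, did not pass as a list. Gli1 measured 35.7 and 36.2 FPKM with an adjusted p of 0.83, and Mycn measured 80.2 and 79.5 FPKM with an adjusted p of 0.87. Of 19 pathway members 4 rose and 2 fell (5 and 3 adjusted over the list alone), with an adjusted camera p of 0.62 and an adjusted p = 0.77 with an estimated correlation. Hhip, a hedgehog-binding inhibitor, rose from 2.53 to 4.39 FPKM, Sufu, an inhibitor of the pathway, rose from 19.8 to 22.6 FPKM, and the Wnt antagonist gene Sfrp1 fell from 81.8 to 68.8 FPKM. Of 41 axon guidance genes 14 rose and 8 fell (15 and 9 adjusted over the list alone), including rises of Ephb1 (7.72 to 10.1 FPKM) and Chl1 (4.58 to 6.67 FPKM) and a fall of Ntn4 (18.8 to 14.3 FPKM), with an adjusted camera p of 0.76 and an adjusted p = 0.87 with an estimated correlation. Reln was a member of both this list and the differentiation list.

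Markers of cell types outside the granule lineage moved with genotype, most of them upward. GABAergic interneuron markers rose in 10 of 12 cases, also adjusted over the list alone, with Gad1 at 6.28 ± 0.36 and 11.2 ± 0.42 FPKM (SD, n = 3), Slc32a1 at 5.40 and 9.77 FPKM and Pax2 at 8.68 and 15.1 FPKM. Their median was 0.61, with an adjusted camera p of 6.9e-08 and an adjusted p = 0.12 with an estimated correlation. Endothelial markers rose in 12 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone), with Tie1 at 9.11 and 17.1 FPKM, Egfl7 at 6.89 and 12.2 FPKM and Kdr at 8.92 and 14.9 FPKM. Their median was 0.63, with an adjusted camera p of 7.1e-09 and an adjusted p = 0.071 with an estimated correlation. Mural and fibroblast markers rose in 10 of 15 cases (10 up and 1 down adjusted over the list alone), with Rgs5 at 17.3 and 28.9 FPKM, Col4a1 at 31.9 and 47.8 FPKM and Vtn at 40.3 and 56.7 FPKM, an adjusted camera p of 1.6e-05 and an adjusted p = 0.071 with an estimated correlation.

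Oligodendrocyte lineage markers rose in 10 of 13 cases (12 up and 1 down adjusted over the list alone), among them Gpr17 (11.6 to 18.9 FPKM) and Cnp (log2 difference 0.47), with an adjusted camera p of 7.5e-06 and an adjusted p = 0.095 with an estimated correlation. Microglia and macrophage markers rose in 11 of 18 cases (14 adjusted over the list alone), among them Mrc1 (5.68 to 9.46 FPKM), Lyz2 (27.9 to 41.0 FPKM) and Csf1r (17.0 to 24.9 FPKM), with an adjusted camera p of 4.8e-08 and an adjusted p = 0.12 with an estimated correlation. Astroglia markers rose in 12 of 20 cases (16 adjusted over the list alone), among them Aqp4 (34.5 to 50.2 FPKM), Gfap (log2 difference 0.52) and Nes (12.4 to 16.0 FPKM), with an adjusted camera p of 6.5e-06 and an adjusted p = 0.095 with an estimated correlation. Purkinje cell markers rose in 4 of 8 cases (5 adjusted over the list alone), with Lhx5 at 21.2 and 33.4 FPKM, Itpr1 at 2.63 and 3.74 FPKM and Car8 at 3.74 and 4.84 FPKM, an adjusted camera p of 0.0060 and an adjusted p = 0.13 with an estimated correlation. Erythroid markers rose in 4 of 5 cases, also adjusted over the list alone, with Alas2 at 8.54 and 12.2 FPKM, Hbb-bs at 527 and 697 FPKM and Hbb-bt at 81.6 and 135 FPKM, an adjusted camera p of 0.021 and an adjusted p = 0.14 with an estimated correlation.

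Choroid plexus and ependyma markers went the other way in part, with a positive difference in 4 of 9 cases and falls in 5 (5 down and 1 up adjusted over the list alone). The falls included Ttr, Aqp1 and the folate receptor gene Folr1, which fell from 6.37 to 3.32 FPKM. The list median was -0.74, with an adjusted camera p of 9.0e-04 and an adjusted p = 0.095 with an estimated correlation. Of 5 markers of unipolar brush and nuclear neurons Otx2 rose from 19.4 to 22.3 FPKM, 1 gene over all genes and 1 adjusted over the list alone, and the list had an adjusted camera p of 0.76 and an adjusted p = 0.77 with an estimated correlation.

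**Figure D3:**
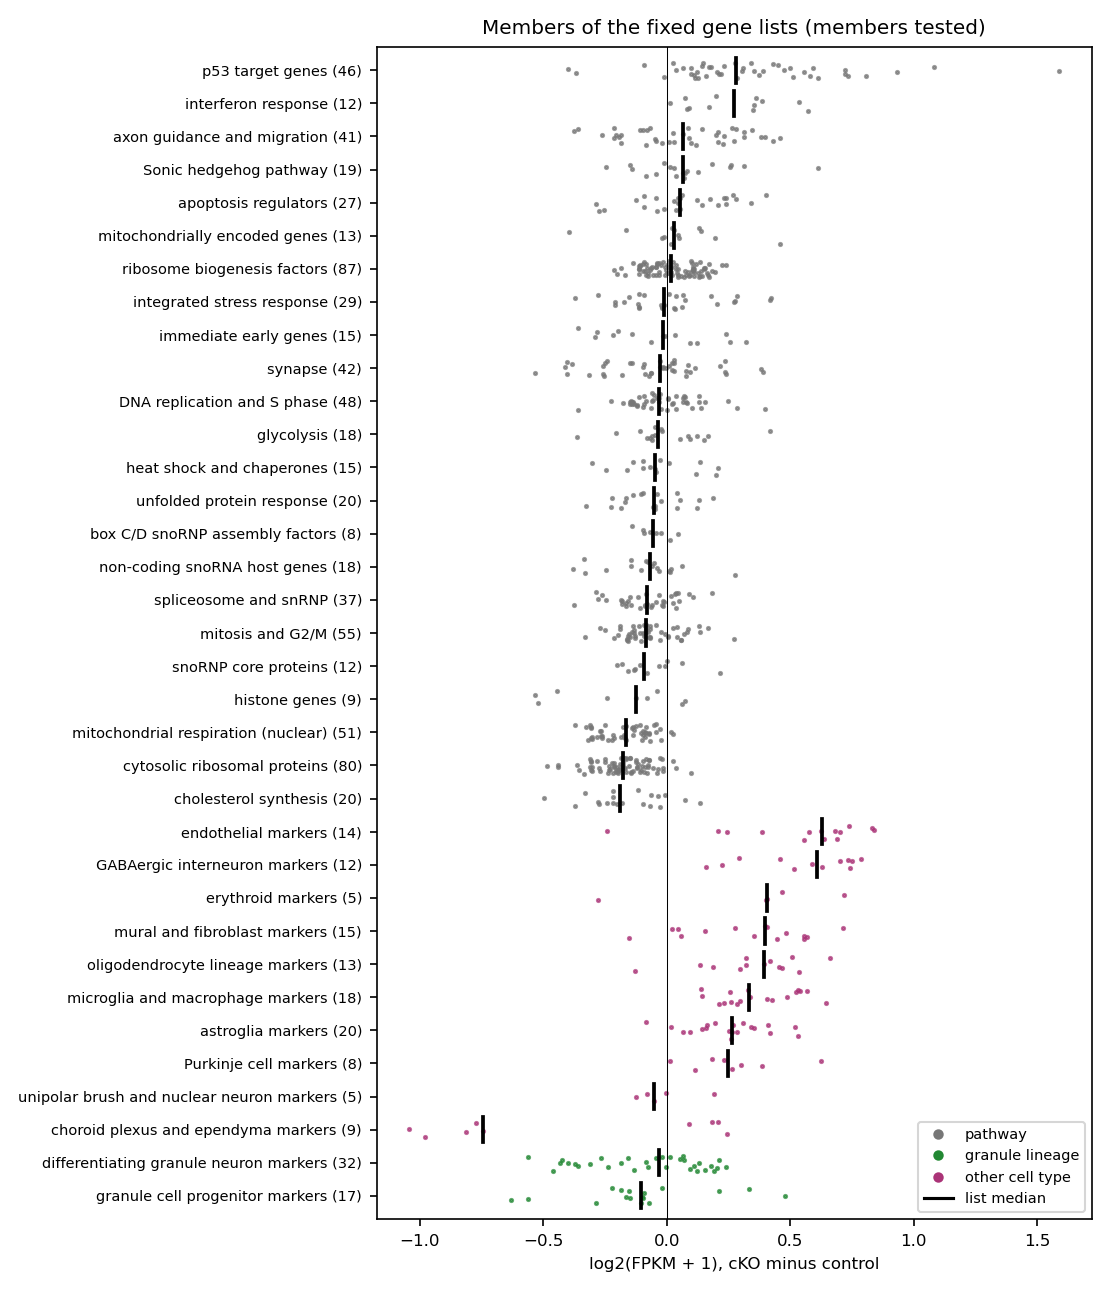
Each point is a tested member of 1 of the 35 fixed gene lists, with its cKO minus control difference in log2(FPKM + 1) on the horizontal axis; black bars are list medians, colours mark the kind of list and the number of tested members stands after each name. The median was 0.28 for p53 target genes, 0.63 for endothelial markers, -0.18 for cytosolic ribosomal proteins and -0.74 for choroid plexus and ependyma markers.

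In all, 24 of the 35 lists passed camera at its preset correlation, 10 higher and 14 lower than the other genes. None passed with an estimated correlation, where 14 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.071. Lists with an estimated correlation below the preset 0.01 also had higher p-values in this form. For cholesterol synthesis the estimate was -0.012, and the unadjusted camera p was 2.3e-07 at the preset and 0.0048 with the estimate. The loss of calls thus does not show that correlation between genes accounts for the shifts. With quantile normalization 17 lists passed, and histone genes, snoRNP core proteins, S phase, the unfolded protein response, spliceosome, progenitor and differentiation markers did not. The test fry, which asks whether the members of a list moved on balance in 1 direction and does not compare them with other genes, passed 24 lists. Among them were apoptosis regulators (higher, adjusted fry p of 0.021), axon guidance (higher, 0.033) and heat shock genes (lower, 0.048), which did not pass camera. Fry did not pass snoRNP core proteins (0.090), S phase (0.46) or histone genes (0.086). Other splits of the same 6 libraries also passed up to 16 lists in camera at the preset correlation. Those splits mix the genotypes unequally, so part of the genotype difference stays between their groups. They thus do not show how many lists would pass without a genotype difference.

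The sex-linked genes differed between the groups, a check made after their values were seen. Xist measured 53.7 ± 3.2 FPKM (SD, n = 3) in control and 24.0 ± 0.51 FPKM (SD, n = 3) in cKO, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in cKO, with Eif2s3y at 9.47 and 17.0 FPKM. Xist and the Y-linked genes were both present in all 6 libraries, so each library probably held cells of both sexes. Xist was close within groups, at 56.4, 50.2 and 54.5 FPKM in control and 24.6, 23.7 and 23.7 FPKM in cKO. Whether the 3 libraries of a group came from 1 pool of animals cannot be told from this. If they did, the SDs and p-values would hold no spread between animals. Of the 2590 changed genes 88 were on X or Y, and 2511 genes changed when genes of X and Y were left out of the fit. Sex makeup followed genotype in these libraries, so an effect of sex on autosomal genes could add to or oppose that of genotype. It was not separated from it.

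The difference between the groups also followed gene length. Length here is the value per gene that the deposited table gives, not the span on the chromosome, which was not examined. For Itpr1 it was 18319 bases, with positions from 108190057 to 108528070. Across 12092 protein-coding genes, which are not independent replicates, Spearman's rho between gene length and the log2 difference was 0.27. The median difference was -0.07 in the decile of shortest genes and 0.10 in that of the longest. After a length trend was removed from each library, 2206 genes changed, 1161 higher and 1045 lower.

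**Figure D4:**
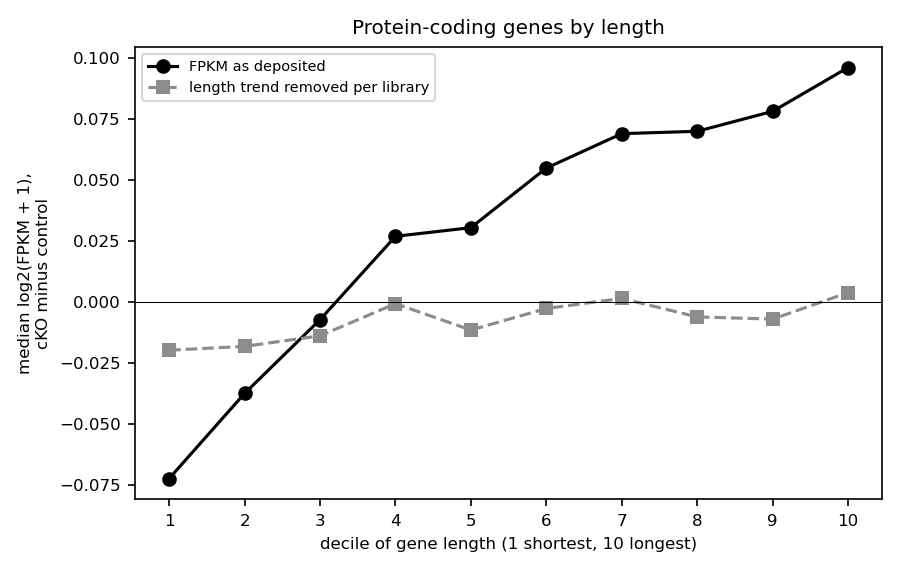
Median cKO minus control difference in log2(FPKM + 1) of protein-coding genes (vertical axis) in 10 equal groups from the shortest to the longest deposited gene length (horizontal axis), as deposited and after a length trend was removed per library. The deposited medians ran from -0.07 to 0.10, and the corrected medians from -0.020 to 0.0038.

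Within 2 Mb of Znhit3, by the positions in the deposited table, 15 of 48 other tested genes changed, 12 higher and 3 lower. Lhx1os fell from 11.7 to 8.25 FPKM and its neighbour Lhx1, a LIM homeobox gene, from 39.1 to 31.8 FPKM. Car4 rose from 7.14 to 9.99 FPKM, Appbp2 from 14.0 to 16.8 FPKM and Slfn9 from 9.67 to 11.9 FPKM.

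The authors' deposited table called 3451 of the genes tested here, 1637 higher and 1814 lower. Of these, 2219 were also called here in the same direction, 1471 higher and 748 lower, and no gene was called in opposite directions. Independent lists of these sizes would share 223 higher and 105 lower genes among the 13204 genes tested in both. Both sets of calls come from the same libraries, so the overlap is not independent evidence, and it fell to 1132 genes without cKO replicate 2, 1237 without control replicate 2, 1370 without control replicate 3, 1416 without cKO replicate 3 and 1175 with no filter on low values.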

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

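The genes in this part lay below the filter of the fit and were looked for after the data had been seen. Hnf4a, which encodes a transcription factor of liver and gut, had 0 reads in the 3 control libraries and 14, 8 and 10 reads in the cKO libraries, 32 in all. Igll1, a component of the pre-B-cell receptor, had 8, 6 and 8 reads in the control libraries, 22 in all, and 0 in the 3 cKO libraries. Both were picked from all genes below the filter for having 0 reads throughout 1 group and at least 5 reads in each library of the other, and neither was tested.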

How the results depend on the processing

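Length and GC correction, voom, protein-coding genes only and omission of X and Y were chosen after seeing the data. The fall of Znhit3 kept its direction and passed in all 20 alternatives, with log2 differences between -0.89 and -0.96 when 1 library was left out. Of 111 called genes named by the rule, 81 stayed called in each alternative that tested them (62 tested in all 20 and 19 in fewer), 30 lost the call in at least 1 and none reversed. Of 24 called lists 17 stayed called in each refit that tested them (12 tested in all 20 and 5 in fewer) and 7 did not, namely histone genes, snoRNP core proteins, S phase, the unfolded protein response, spliceosome, progenitor markers and differentiation markers; quantile normalization ended the call of all 7. Called genes and lists without a value numbered 17 and 4 at a mean of at least 5 FPKM, 10 and 1 among protein-coding genes, 6 and 1 without X and Y, and 2 and 0 with length and GC correction.

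The count of changed genes was 1271 with no filter on low values, where 31091 genes were tested, and between 1207 and 2195 with 1 library left out. In the other direction it was 3721 with array weights, 3718 with voom, 3171 among protein-coding genes and 2997 with TPM scaling. A size filter of 1.5-fold in place of 2-fold kept 196 genes. Changes of over 2-fold numbered 61 with a pseudocount of 0.1, 48 with TPM scaling, 75 with voom, 13 at a mean of at least 5 FPKM and 8 among protein-coding genes, and between 21 and 28 with 1 library left out. Genes shared with the authors' calls numbered 1175 with no filter, and between 1132 and 1853 with 1 library left out. The number of lists passing was 0 with an estimated correlation, 24 with fry (not all the same lists) and between 21 and 24 with 1 library left out. With no filter more genes enter the adjustment, and with a library left out fewer samples enter the fit; beyond that the cause was not tested.

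With a replicate block 1542 genes changed and 1446 were shared with the authors' calls. Libraries of the same number did not deviate together (correlations of -0.02, 0.04 and -0.10), and not every library correlated best with its own number, so the numbers were not taken as pairs.

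Lists that did not pass changed direction in camera in some settings, none past the threshold, and the cause was not tested. The medians of ribosome biogenesis factors were then 0.0153 with no filter, 0.0147 at a mean of at least 5 FPKM, -0.0105 with quantile normalization and 0.0561 with TPM scaling, and lay between -0.00219 and 0.0363 with 1 library left out. Those of mitochondrially encoded genes were 0.0309 with no filter, at a mean of at least 5 FPKM and with the replicate block, 0.145 with quantile normalization, 0.0875 with length correction and 0.0381 with length and GC correction, and lay between -0.0392 and 0.108 with 1 library left out. Those of the Sonic hedgehog pathway were 0.0221 at a mean of at least 5 FPKM and -0.0144 with length correction. Those of axon guidance were -0.0317 at a mean of at least 5 FPKM, 0.0183 with length correction and 0.0170 with length and GC correction, and lay between 0.0156 and 0.0883 with 1 library left out. Glycolysis was at 0.0265 with quantile normalization. The difference of mt-Co1 lay between -0.0165 and 0.0882 with 1 library left out. The alternatives planned only for a table of counts were not run, since the table holds FPKM, while voom was run on the reads recovered from it. Depth limits the genes with few reads, such as Mir99a and Mir7664.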

Other observations

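Of the tests in this part, the comparisons of p53 targets with other cell types, the permutations of marker lists, the random lists, the tests of scale and of the pseudocount and the Fisher test near Znhit3 were chosen only after the result was seen. Several pathway lists not described above passed camera at its preset correlation. Of 12 interferon response genes 3 rose and none fell (4 adjusted over the list alone), among them Trim25 (2.19 to 3.75 FPKM), Irf9 (2.86 to 3.94 FPKM) and Gbp3 (0.74 to 1.28 FPKM), with an adjusted camera p of 0.018 and an adjusted p = 0.12 with an estimated correlation. The interferon median was 0.27, in libraries where the medians of microglia and endothelial markers were 0.33 and 0.63. Of 20 genes of the unfolded protein response 4 fell, also adjusted over the list alone, among them Manf (32.2 to 25.4 FPKM), Hspa5 (128 to 112 FPKM) and Creld2 (30.5 to 25.8 FPKM), with an adjusted camera p of 0.0096 and an adjusted p = 0.12 with an estimated correlation. Of 37 spliceosome genes 3 fell, Snrpe (80.1 to 65.6 FPKM), Snrpd1 (63.0 to 51.8 FPKM) and Sf3a3 (50.6 to 44.6 FPKM), and none adjusted over the list alone, with an adjusted camera p of 9.0e-04 and an adjusted p = 0.12 with an estimated correlation. The falls of the last 2 lists came from libraries in which 8 marker lists of other cell types had medians of 0.25 to 0.63.

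Stress and activity genes were mixed. Of 29 genes of the integrated stress response 4 rose and 5 fell, also adjusted over the list alone, with rises of Jdp2 (2.11 to 3.15 FPKM) and the amino acid transporter gene Slc7a5 (117 to 142 FPKM) and a fall of Herpud1 (22.6 to 19.3 FPKM), and camera gave an adjusted p of 0.34 (adjusted p = 0.56 with an estimated correlation). Of 15 immediate early genes 3 rose and 4 fell, also adjusted over the list alone, with Fos at 39.8 and 32.4 FPKM, Dusp1 at 19.7 and 15.1 FPKM and Ier5 at 56.5 and 70.8 FPKM (camera adjusted p of 0.15, and adjusted p = 0.55 with an estimated correlation). Of 18 glycolysis genes Gapdh (285 to 221 FPKM) and Tpi1 (94.4 to 81.8 FPKM) fell and the glucose transporter gene Slc2a1 rose (16.6 to 22.6 FPKM), with the same counts adjusted over the list alone (camera adjusted p of 0.34, and adjusted p = 0.66 with an estimated correlation). Of 15 heat shock genes Hspa8 fell from 549 to 445 FPKM, 1 gene also adjusted over the list alone (camera adjusted p of 0.11, and adjusted p = 0.22 with an estimated correlation).

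Processed pseudogenes made up 9 of the 23 genes that changed by over 2-fold, 2 higher and 7 lower. The largest change of all was in the pseudogene Gm4739, which rose from 3.01 ± 0.11 to 29.6 ± 1.8 FPKM (SD, n = 3). Rpsa-ps10 fell from 210 to 76.6 FPKM while its parent gene Rpsa measured 471 and 443 FPKM with an adjusted limma p of 0.22. Within 2 Mb of Znhit3, 31.3% of tested genes changed against 19.1% of all others, with a Fisher exact p of 0.042. That test treats genes as independent, which neighbouring genes from the same libraries are not, so its p may be too small.

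Of 46 p53 targets 26 rose and 1 fell, and the list did not pass with an estimated correlation (adjusted p = 0.071). After the length trend was removed the median of the list was 0.24, with an adjusted camera p of 2.8e-12 and an adjusted p = 0.055 with an estimated correlation, and 10000 random lists matched on length and expression had medians from -0.03 to 0.08 (95% range), so length was not the whole of the shift. The lower 95% bound of the log2 difference of Cdkn1a was 1.49, above the upper bound of each of the 119 markers of other cell types, the highest of which was 1.06 for Hbb-bt. Cdkn1a was chosen for its large rise in these data, and a rise of Cdkn1a within other cells was not tested. The comparison thus does not decide whether other cells contributed to it. The list median of 0.28 lay below the upper 95% bound of the highest marker list median, 0.74, so for the list a contribution of other cells cannot be told apart from a response of the progenitors to Znhit3 loss. Sex makeup, which also differed between the groups, was not tested as an explanation.

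Of 80 cytosolic ribosomal protein genes 18 fell and of 51 nuclear respiratory genes 9, and neither list passed with an estimated correlation (adjusted p = 0.12 each). After the length trend was removed the list medians were -0.16 and -0.14, so length was not the whole of either shift in the deposited values. The adjusted camera p-values were then 2.6e-08 and 1.1e-06 at the preset correlation, and 0.095 for each list with an estimated correlation. Among 10000 random lists matched on length and expression the medians ran from -0.12 to -0.05 for the first list and from -0.13 to -0.04 for the second (95% ranges), against -0.18 and -0.16 observed. The estimated correlations within the 2 lists were 0.17 and 0.14, so ranges from random lists may be too narrow. With quantile normalization the respiratory median of -0.11 still lay below its random lists (-0.086 to 0.0031), while the ribosomal median of -0.060 lay among them (-0.080 to -0.0094) and passed camera (adjusted p of 0.012). With TPM scaling the ribosomal median of -0.14 lay below its random lists (-0.084 to -0.016). The outcome for ribosomal proteins thus depended on the scaling. A change of these genes cannot be told apart from a different scale of abundant genes between libraries. RNA quality and a shift of cell types were not tested for either list.

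Of 105 markers in the 8 lists of other cell types that were higher in camera 73 rose and 1 fell. Of 9 choroid plexus and ependyma markers 5 fell and 4 had a positive difference. None of these lists passed with an estimated correlation (adjusted p between 0.071 and 0.14). A single lower share of granule lineage cells would raise by about the same fold only markers that granule lineage cells do not express. The list medians lay further apart than in permuted lists (permutation p = 1e-04, the smallest that 10000 permutations can give). That p was the same with a pseudocount of 0.1 and with voom, which understate low genes less, and among the 8 lists that rose it was 0.014, with 0.0032 and 0.0022 in these 2 settings. The permutation treats markers as independent, while the estimated correlation was 0.28 for GABAergic interneuron and 0.21 for microglia markers. These p-values may thus be too small and do not decide against a single lower share among the lists that rose. Such a share would not by itself lower markers of other cells, so it leaves the 5 falls of choroid plexus and ependyma markers unexplained. After length correction the median of the 105 members of those lists was 0.36, so the length trend did not account for the whole rise. Different yields of single cell types at dissection, and a change within those cells, may both contribute and were not separated.

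With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05, so these counts cannot exclude chance. The split by genotype was the 1 split with as many changed genes (2590, against 0 in the highest other split), as many over 2-fold (23 against 0), as many shared with the authors' calls (2219 against 0) and as many lists (24 against 16). Every other split mixes genotypes unequally within both groups. This puts genotype difference into the spread and also leaves part of it between the groups, so lists passing there are not free of genotype. Counts of 0 there thus say little, and with 0 called genes none could be shared with the authors' calls.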
